A study of Homo sapiens with 4 samples.

How the data were processed

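The samples were 4 preparations of MCF-7, an estrogen receptor positive human breast adenocarcinoma cell line, and each gave a library from polyadenylated RNA. Per the labels, 2 samples received a control PROTAC and 2 received P-SETDB1-4, both delivered with the PEI transfection reagent. A PROTAC is a molecule that brings a chosen protein to a ubiquitin ligase so that the protein is degraded. Here the series title names SETDB1 as the target and a ligand of the ligase subunit CRBN as the recruiting part. RNA was extracted with Trizol and prepared for Illumina sequencing, per the labels' protocols. Dose, time of exposure, read length and strand setting are not given in the sources used here. The labels do not say whether the samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

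The authors deposited 1 table with whole-number read counts for 16592 genes and 1141 transposable element (TE) subfamilies in 4 columns. STAR 2.7.9a and the human build hg38 (GRCh38) are named in the submitters' processing notes, and the column names of the deposited count table are those of coordinate-sorted STAR alignments, per the file headers. The counting tool, the gene annotation and the treatment of reads that align to several places are not given in the sources used here. The table's title calls its values normalized, but the deposited counts are whole numbers whose column totals differ, and each column's median ratio to the row mean followed its total. That ratio was 1.11 for control replicate 1, whose total was 1.10 times the mean total, and 0.900 for control replicate 2, whose total was 0.898 times the mean. No scaling for depth was therefore assumed, and the values were treated as raw counts. Each row's largest count was at least 2, so rows nearly without reads had already been left out. The labels tie each column to a sample. The columns are numbered 2 and 3 within each group where the sample titles say replicate 1 and 2; the replicate numbers below are those of the titles. A TE row sums over every copy of a subfamily in the genome and has no position of its own.

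The design written before the data were examined assumed log2 values tested with limma and named edgeR's quasi-likelihood test for the case that the table held raw counts. That test was therefore the main one (edgeR 4.0.16 in R 4.3.3, glmQLFit and glmQLFTest, two-sided), with TMM scaling factors and all 4 libraries in the fit. Gene and TE rows with a mean of at least 10 counts were fitted together, which left 13779 genes and 1017 TE rows holding 99.954% of the counts. P-values were adjusted over these 14796 rows by the Benjamini-Hochberg method, and a row was called at an adjusted p under 0.05. A change is given as the log2 fold change of P-SETDB1-4 over control with its standard error (SE), and a level as CPM (the count scaled to the library total and the TMM factor) with its SD over 2 libraries; a value after ± is an SE unless given with a level. Gene symbols came from a table of gene identifiers, which matched 16569 of the 16592 gene rows, and positions came from GENCODE release 29 on GRCh38. 21 symbols occur on more than 1 row. Genes that share sequence with near-identical copies, such as histone and ribosomal protein genes, may have gained or lost reads to those copies, since the treatment of such reads is unknown. Without a known strand setting, overlapping antisense genes cannot be separated.

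Gene lists were fixed before the data were examined, and 46 gene and TE lists with at least 5 tested rows were tested with camera (limma 3.58.1, inter-gene correlation preset to 0.01). Camera asks whether a list's genes rank above or below the other rows. It was repeated with an estimated correlation, and fry was run beside it, which asks whether a list's genes move, on balance, one way. With so few libraries the repeat has few residual degrees of freedom, so a call lost in it need not reflect correlated members. The list of abundant noncoding RNAs had 1 tested member, TUG1, and was not tested. The SVA list holds the same 6 rows as the Retroposon class. Lists overlap, and apoptosis genes share 5 members with p53 target genes.

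Genes named in the text were chosen by a rule fixed before the data were examined. It took the 12 largest rises and the 12 largest falls among called genes with a mean of at least 50 counts and no overlap between the groups, SETDB1 and TRIM28, and the 4 members of each list with the smallest p. For TE rows it took the 6 smallest p-values in each direction and L1HS, HERVK-int, HERVH-int and SVA_D. Other list members, named where a list had 5 or fewer calls in a direction, as well as ATF7IP, CRBN, 7SK, TUG1 and rows named only in the closing part, were chosen after the values were seen.

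The fit was tested on simulated data drawn from the tested rows' means, the library sizes and the fitted dispersions, with 50 genes changed at each of 4 sizes. It called 43 of 50 genes raised 1.5-fold, 34 of 50 genes lowered to 0.667 of their level, 49 of 50 raised 2-fold and 45 of 50 lowered to 0.5 of their level. It also called 4 of 14596 unchanged rows. Camera called the shifted list, the p53 target genes, and also 1 of the 45 other lists. With an estimated correlation it called the shifted list (adjusted p = 0.0319 with an estimated correlation) and no other. Some of the other lists hold shifted members, 5 in the apoptosis list, so that 1 call need not be false. Rows were drawn independently, so the simulation cannot compare a preset with an estimated correlation.

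Alternatives were no filter on low counts, a mean of at least 50 counts, TMM factors from gene rows, quantile normalization, limma on unscaled log2 values with pseudocounts of 0.5 and 8 and without its variance trend, DESeq2 1.42.0, the replicate number as a block, and each library left out in turn. Median-of-ratios factors, library totals and limma on log2(count + 1) were added after the data had been seen, as were other choices of near-silent genes in the test of genomic DNA. Where a named gene, TE row or gene list changed call under one of these, the text gives the adjusted p there. Limma on unscaled values is left out of this. TE lists were not followed singly under these alternatives, only in the number of lists called, which did move. C1, C2, P1 and P2 stand for the control or P-SETDB1-4 replicate left out. A log2 value follows where it moved by more than 1.5 times. Library totals were 23652812 and 19317730 counts for control and 21098881 and 22223643 for P-SETDB1-4. The biological coefficient of variation was 3.11%, from a common dispersion of 0.000969. Replicates were compared by chi-square over the tested rows: the statistic per degree of freedom was 1.49 between the controls, 3.05 between the P-SETDB1-4 libraries and between 14.3 and 16.5 across groups. Both replicate pairs differed by more than counting noise, which repeat preparations of 1 culture can also give, so this does not show that they were separate cultures. Intervals on shares are Wilson 95% intervals and cover counting error only. Groups of 2 are too small for a test of outlying samples or for counting other splits of the samples. Figures were drawn with matplotlib 3.10.9.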

Results

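RNA from 2 control MCF-7 samples and 2 samples transfected with P-SETDB1-4 was compared by polyA-selected RNA sequencing over genes and TE subfamilies. Total counts ranged from 19317730 to 23652812 per library. A count was present for 16097 and 16006 genes in the control libraries and for 16076 and 16079 genes in the P-SETDB1-4 libraries. The 10 highest rows took between 9.05% and 9.39% of the counts of a library.

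The first comparison asked whether the transcript of the targeted protein differed. SETDB1 (ENSG00000143379.13; chromosome 1, 150926263 to 150964744, plus strand, GRCh38), a methyltransferase that deposits H3K9 trimethylation, fell by 0.24 ± 0.05 on the log2 scale (edgeR adjusted p = 0.00288). Its level was 87.3 ± 0.873 CPM in control and 73.9 ± 3.78 CPM in P-SETDB1-4 (SD, n = 2 each), from counts of 2091 and 1680 against 1605 and 1575. Its stabilising partner ATF7IP fell by 0.27 ± 0.06 (edgeR adjusted p = 0.00239), whereas the corepressor TRIM28 did not pass the test (0.11 ± 0.04, edgeR adjusted p = 0.0508). CRBN, the substrate receptor of the recruited ligase, was at 31.9 ± 2.15 CPM in control and 31.6 ± 1.72 CPM in P-SETDB1-4 and was not called (edgeR adjusted p = 0.936), with a log2 change of -0.08 (C1), 0.06 (C2), -0.06 (P1) and 0.05 (P2) when a library was left out. A PROTAC acts on the protein, which was not measured here, so the mRNA level is no check of the labels. An alternative gave a call for TRIM28 (stricter filter 0.0309, gene-row TMM 0.0277, limma on gene-row TMM 0.0260, quantile 0.0348, P2 0.0142).

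Among 30 tested genes of the H3K9 methylation and silencing machinery, 8 were lower, 2 were higher and 20 were not called; adjusted over the list alone, 9 were lower and 3 higher. KDM4C and KDM4A, which remove H3K9 methylation, fell by 0.59 and 0.31, and PPHLN1, a member of the HUSH complex, fell by 0.34. The H3K9 methylation readers CBX3 and CBX5 rose, by 0.22 ± 0.04 and 0.18 ± 0.04. The list had a median log2 change of -0.093. Genes with long spans on the genome tended to be lower (described below), with a median of -0.132 in the group with the longest spans. Whether span explains the fall of this list was not tested. Camera placed the list below the other rows (adjusted p = 0.0328), a call that was lost otherwise (adjusted p = 0.424 with an estimated correlation). Those other rows include the TE rows, which rose as a group, and a comparison with gene rows alone was not run. The fry test gave an adjusted p of 0.0173. The camera call also ended with the stricter filter (0.0575), with quantile normalization (0.0691) and for P1 (0.0699). Of 13 genes of the CRBN ligase and its known substrates, GSPT1 (-0.30), CUL4A (-0.21) and ZFP91 (-0.18) were lower and CSNK1A1 (0.12) was higher (adjusted over the list alone, 3 lower and 1 higher; camera adjusted p = 0.346). Under an alternative the call ended for CSNK1A1 (DESeq2 0.0653, C1 0.204, C2 0.250, totals 0.0526), CUL4A (C1 0.0914, C2 0.0522), ZFP91 (C1 0.0774, C2 0.151) and CBX5 (C1 0.122).

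The second comparison asked which genes differed between the treatments. The most raised gene by the fixed rule was SHANK1, a scaffold protein of synapses (chromosome 19, 50661827 to 50719450, minus strand), which went from 0.527 ± 0.0879 to 10.4 ± 0.819 CPM (log2 change 4.28 ± 0.20, edgeR adjusted p = 4.12e-09). Its control level rested on 14 and 9 counts, against 207 and 244 with P-SETDB1-4. LEKR1 (chromosome 3, 156825481 to 157046129, plus strand) rose from 2.33 ± 0.205 to 15.3 ± 0.111 CPM, and HCFC1R1 (chromosome 16, 3022620 to 3024286, minus strand) rose from 28.6 ± 1.09 to 96.6 ± 7.47 CPM. Among genes that met the rule, the largest fall was that of TMEM156, a gene for a transmembrane protein (chromosome 4, 38966744 to 39032922, minus strand), from 6.26 ± 0.310 to 1.83 ± 0.226 CPM (log2 change -1.77 ± 0.17, edgeR adjusted p = 3.74e-06). SLC16A2, a thyroid hormone transporter (chromosome X, 74421461 to 74533917, plus strand), fell from 25.2 ± 1.45 to 11.6 ± 1.10 CPM.

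The other large rises were those of the zinc finger transcription factor gene EGR4 (2.12 ± 0.26), ASPG (1.96 ± 0.22), ZSCAN31 (1.68 ± 0.12), the carbonic anhydrase gene CA14 (1.63 ± 0.17) and the histone genes H3C2, H2AC17, H3C12, H3C13 and H2BC7, between 1.67 and 1.77. H2AC17 and H3C12 overlap on the minus strand of chromosome 6, so their reads may be shared. Among the falls, IL1RL1, the gene for the interleukin 33 receptor, fell by 1.52 ± 0.24, the cytokine gene IL32 by 1.07 ± 0.22 and the interferon-stimulated gene DDX60 by 1.04 ± 0.22. ANKRD31 (-1.52), FBXW10B (-1.18), the ammonia transporter gene RHCG (-1.07), LPXN (-1.05), CCDC33 (-1.05), the myosin gene MYO16 (-1.04) and TMEM40 (-0.96) made up the rest. FBXW10B has close paralogs, and its value is uncertain for that reason. A left-out library moved RHCG to -0.65 without P-SETDB1-4 replicate 1 and -1.70 without P-SETDB1-4 replicate 2.

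**Figure D1:**
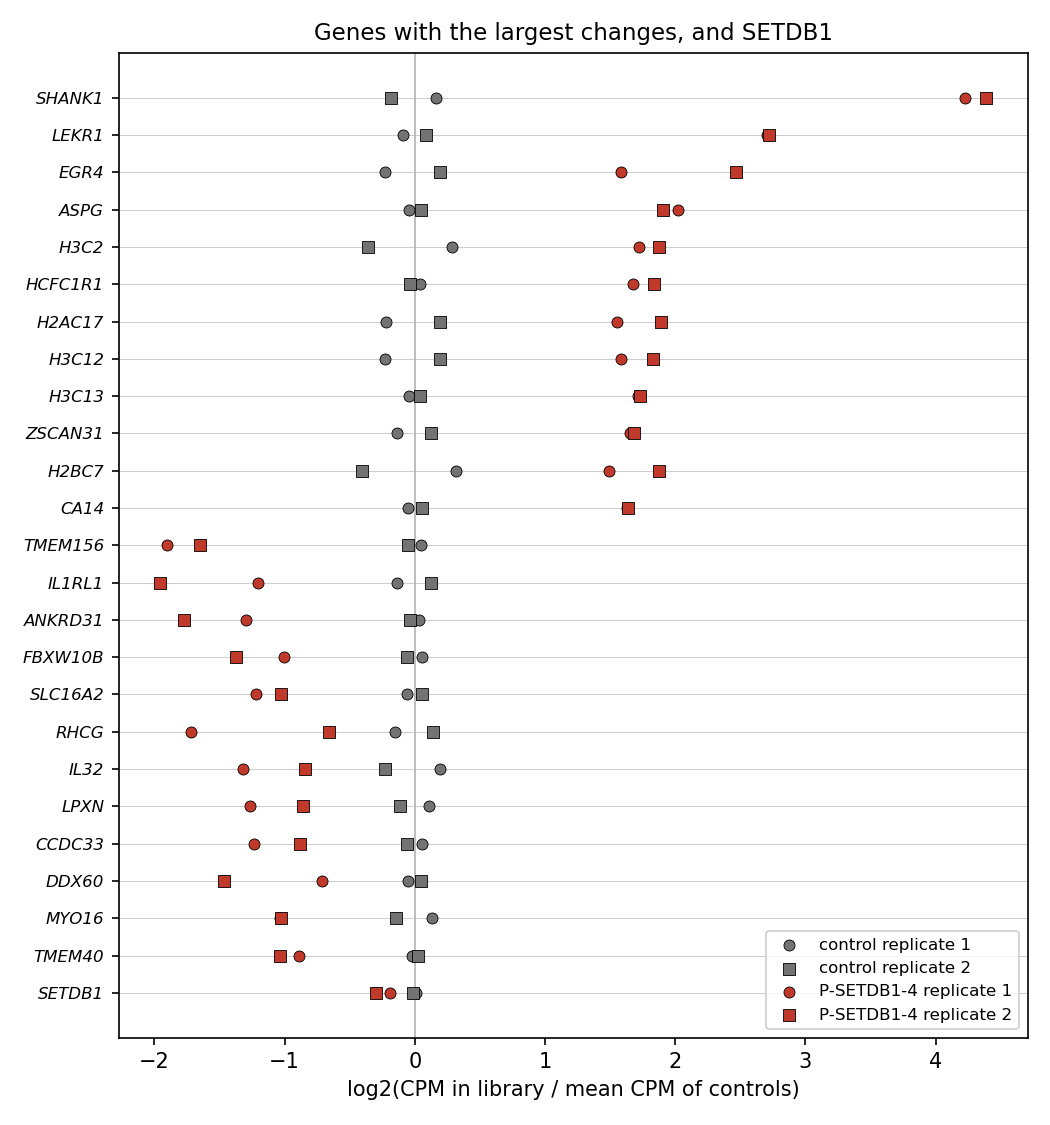
Level of each gene with a large change, and of SETDB1, in the 4 libraries, as log2 of CPM over the mean CPM of the controls (circles, replicate 1; squares, replicate 2; grey, control; red, P-SETDB1-4). SHANK1 lies furthest to the right (log2 change 4.28) and TMEM156 furthest to the left by its mean (-1.77). In each gene shown the red points lie apart from the grey ones, which the selection rule required of every gene but SETDB1.

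In all, 1780 of 13779 tested genes were higher and 2334 were lower with P-SETDB1-4. A change of at least 2-fold was seen in 150 of the higher and 41 of the lower genes, and the median size of a called change was 0.29 on the log2 scale. The count moved by more than 1.5 times without control replicate 1 (1076 higher and 1424 lower), without control replicate 2 (1051 and 1287) and with DESeq2 (953 and 1441). On unscaled log2 values limma called 165 higher and 66 lower, so the share of higher genes among calls was 71.4% there and 43.3% in the edgeR fit.

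Genes with a short span on the genome tended to be higher, and genes with a long span lower, a relation examined after the values were seen. With genes ranked by span and split into 5 groups of equal size, the group with the shortest spans (up to 10.36 kb) had a median log2 change of 0.10, with 670 genes higher and 109 lower. The group with the longest spans (from 96.4 kb) had a median of -0.13, with 91 higher and 889 lower.

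Known targets of the transcription factor p53 were mostly higher with P-SETDB1-4. Of 37 tested, 30 were higher, 2 were lower and 5 were not called, with a median log2 change of 0.44; adjusted over the list alone, 31 were higher and 2 lower. CDKN1A, an inhibitor of cyclin-dependent kinases, rose from 176 ± 3.65 to 362 ± 12.2 CPM (1.05 ± 0.04, edgeR adjusted p = 6.10e-10), and the growth arrest gene GADD45A rose from 71.7 ± 1.33 to 143 ± 1.46 CPM (0.99 ± 0.05). The antiproliferative gene BTG2 (0.91 ± 0.05) and FDXR (0.93 ± 0.06), which encodes ferredoxin reductase, also rose. The lower members were DDB2 (-0.23 ± 0.05), a DNA damage sensor, and PLXNB2 (-0.14 ± 0.05), a semaphorin receptor. Camera placed the list above the other rows, TE rows included (adjusted p = 2.06e-34, or adjusted p = 0.214 with an estimated correlation), and fry gave 0.00234. Calls that an alternative ended, with the adjusted p, were those of PLXNB2 (C1 0.146, C2 0.160, P1 0.0984 at -0.08).

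Apoptosis genes included 10 higher and 3 lower of 31 (adjusted over the list alone, 11 and 3). BBC3 (1.56 ± 0.10) and PMAIP1 (1.27 ± 0.08), which encode proapoptotic BCL2 family proteins, and the death receptor gene FAS (0.83 ± 0.10) rose, as did CYCS (0.52 ± 0.04), which encodes cytochrome c. The caspase genes CASP9 (-0.60) and CASP8 (-0.25) and the apoptosis inhibitor gene BIRC3 (-0.36) fell. Camera gave an adjusted p of 0.000875 (adjusted p = 0.350 with an estimated correlation), and fry 0.0229. Of these 31 genes, FAS, BAX, BBC3, TNFRSF10B and PMAIP1 are also on the p53 list; among the remaining 26, 5 were higher and 3 lower, and camera gave an unadjusted p of 0.174. An alternative ended the call of BIRC3 (DESeq2 0.0993, C1 0.144) and CASP8 (DESeq2 0.145, C1 0.199, P2 0.0798).

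Immediate early genes, which respond within minutes to growth factors and stress, had 16 of 31 members higher and 3 lower (adjusted over the list alone, 19 and 3). ATF3 (0.98 ± 0.06) and IER5 (0.91 ± 0.05) rose, whereas KLF10 (-0.65 ± 0.04), NR4A3 (-0.66 ± 0.12) and CCN1 (-0.22 ± 0.06) fell. The camera call (adjusted p = 5.26e-10) was lost otherwise (adjusted p = 0.431 with an estimated correlation), and fry gave 0.0993. No longer called under an alternative were CCN1 (DESeq2 0.0674, C1 0.128, C2 0.0617).

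Replication-dependent histone genes, whose transcripts normally end in a stem-loop and not in a polyA tail, showed the largest median change of the gene lists, 0.81. Of 57 tested, 40 were higher, 6 lower and 11 not called (adjusted over the list alone, 42 higher and 6 lower). H2BC21 rose from 72.2 ± 3.86 to 187 ± 5.55 CPM (1.38 ± 0.05, edgeR adjusted p = 3.40e-10), H2AC13 rose by 1.32 ± 0.09 and H2BC26 by 1.45 ± 0.12. Camera gave an adjusted p of 2.06e-21 (adjusted p = 0.384 with an estimated correlation) and fry 0.0443. The 7SK row sums over all copies of a repeat named for the noncoding 7SK RNA, which also lacks a polyA tail. This row rose by 1.30 ± 0.19, and its counts were 776 and 1409 in the P-SETDB1-4 libraries against 561 and 330 in control. Histone genes are close copies of each other, so single members are uncertain. A left-out library moved 7SK to 0.85 without P-SETDB1-4 replicate 2.

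Cytosolic ribosomal protein genes had 32 of 79 members higher and 5 lower, with a small median change of 0.09 (adjusted over the list alone, 39 and 7). RPS27 (0.29), RPS2 (0.25) and RPS9 (0.29) rose, and RPS4X (-0.33), RPL35A (-0.21), RPL11 (-0.16), RPL23 (-0.15) and RPL36A (-0.12) fell. The camera adjusted p was 0.000137 (adjusted p = 0.623 with an estimated correlation), and fry gave 0.14. The group of tested genes with the shortest spans had a median of 0.099, no smaller than that of this list. Whether span explains the rise of this list was not tested. Under an alternative the call ended for RPL36A (gene-row TMM 0.0521, limma on gene-row TMM 0.0517, C1 0.297, C2 0.0776, P2 0.113 at -0.07), RPS2 (quantile 0.136 at 0.08) and RPL23 (C1 0.143, C2 0.0713).

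**Figure D2:**
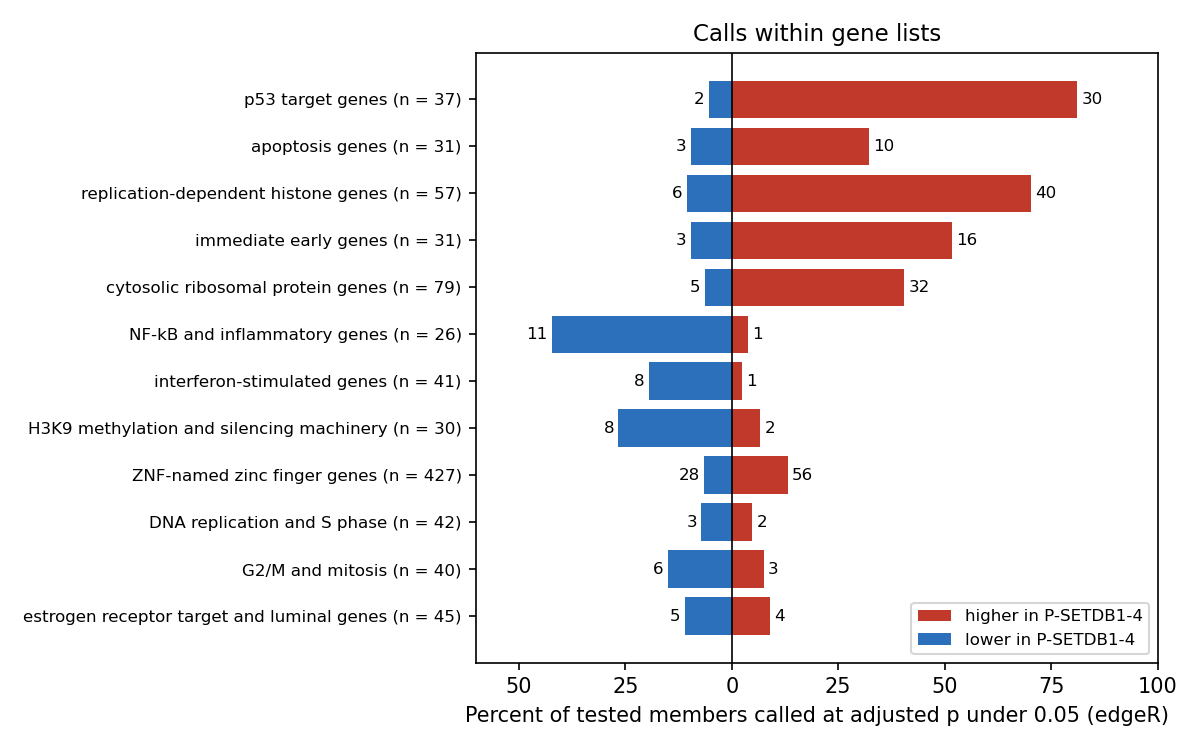
Percent of tested members called higher (red, right) and lower (blue, left) in P-SETDB1-4 for 12 gene lists fixed before the data were examined, with the number of called genes at each bar end and the number tested in brackets. The p53 target genes (30 higher, 2 lower) and histone genes (40 higher, 6 lower) extend furthest to the right, and NF-kB and inflammatory genes (11 lower) furthest to the left.

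NF-kB and inflammatory genes were more often lower: 11 of 26 were lower and NFKBIZ (0.33 ± 0.07) was the only 1 called higher (adjusted over the list alone, 12 and 1). The NF-kB subunit genes RELA and NFKB1 fell by 0.49 ± 0.06 and 0.41 ± 0.06, the cytokine gene IL6 by 0.72 ± 0.13 and the signalling adaptor gene TRAF1 by 0.82 ± 0.16. The camera adjusted p was 0.00556, lost otherwise (adjusted p = 0.530 with an estimated correlation; 0.0657 for P1), and fry gave 0.0837. Calls that an alternative ended, with the adjusted p, were those of NFKBIZ (C2 0.0532).

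Interferon-stimulated genes had 8 of 41 members lower and 1 higher (adjusted over the list alone, 8 and 1), and the list was not called (camera adjusted p = 0.200). PARP14 (-0.49 ± 0.08), the exonuclease gene ISG20 (-0.40 ± 0.06) and DDX60 fell, and SAMD9 (0.56 ± 0.08) rose. Of 13 genes for nucleic acid sensing, the double-stranded RNA sensors RIGI (-0.45 ± 0.12) and EIF2AK2 (-0.18 ± 0.07) fell and the RNA editing enzyme gene ADAR (0.16 ± 0.04) rose; TRAF3 (-0.13 ± 0.05) was not called (adjusted over the list alone, 1 higher and 1 lower; camera adjusted p = 0.589). Among 19 genes of MHC class I antigen presentation, PSMB10 (0.41 ± 0.08) and HLA-E (0.26 ± 0.06) rose and the peptidase gene ERAP2 (-1.06 ± 0.38) fell, while PSMB9 (-0.52 ± 0.19) was not called (adjusted over the list alone, 2 higher and 0 lower; camera adjusted p = 0.711). An alternative ended the call of ERAP2 (no filter 0.0579, limma on gene-row TMM 0.0519, C1 0.0516, C2 0.253, P1 0.115, P2 0.113), EIF2AK2 (gene-row TMM 0.0637, limma on gene-row TMM 0.0593, quantile 0.106, DESeq2 0.0829, C2 0.251, P2 0.349 at -0.07), RIGI (DESeq2 0.0837, P2 0.0740) and ADAR (C1 0.114, C2 0.0906). Called under an alternative were PSMB9 (no filter 0.0360, stricter filter 0.0496, quantile 0.0289, P1 0.0331, totals 0.0465) and TRAF3 (totals 0.0475). A left-out library moved EIF2AK2 to -0.31 (P1) and the uncalled PSMB9 to -0.34 (P2).

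Few cell cycle genes were called. Of 42 genes of DNA replication and S phase, GINS3 (0.31) and MCM5 (0.16) were higher and CDC7 (-0.24), POLA1 (-0.21) and CDC45 (-0.17) lower; adjusted over the list alone none was called in edgeR (0 higher and 0 lower), and the camera adjusted p was 0.969. Of 40 genes of G2/M and mitosis, 6 were lower, among them ANLN (-0.24) and RACGAP1 (-0.22), both needed for cytokinesis, and CKS2 (0.33), SPC25 (0.35) and BIRC5 (0.23) were higher (adjusted over the list alone, 4 lower and 3 higher; camera adjusted p = 0.451). The direction over the estrogen receptor target and luminal list was likewise not called (camera adjusted p = 0.546), with 4 of 45 higher and 5 lower (adjusted over the list alone, 4 and 5). Its lower members were MYBL1 (-0.48), the luminal transcription factor gene GATA3 (-0.24), SIAH2 (-0.23), FHL2 (-0.19) and GREB1 (-0.14), and its higher ones HSPB8 (0.23), CELSR2 (0.20), STC2 (0.16) and FOXA1 (0.13). No longer called under an alternative were CDC45 (gene-row TMM 0.0661, limma on gene-row TMM 0.0652, quantile 0.0898, replicate block 0.0646, DESeq2 0.189, C1 0.171, C2 0.275, P1 0.0642, P2 0.0523), FHL2 (gene-row TMM 0.0502, limma on gene-row TMM 0.0503, DESeq2 0.177, C1 0.141, C2 0.216, P1 0.0574), MCM5 (replicate block 0.0691, DESeq2 0.136, C1 0.0799, C2 0.346, P2 0.244 at 0.09, median of ratios 0.0511, totals 0.0642), GINS3 (DESeq2 0.122, C1 0.0531, C2 0.0868, P1 0.0749), POLA1 (DESeq2 0.0990, C1 0.146, C2 0.0836, P2 0.0522), CDC7 (DESeq2 0.156, C1 0.107, C2 0.127, P1 0.123), STC2 (C1 0.133), SPC25 (C1 0.0984), FOXA1 (C1 0.310, C2 0.0820, P2 0.0514), HSPB8 (C1 0.0648, C2 0.0776), SIAH2 (C1 0.0922, C2 0.0520) and GREB1 (C1 0.143, C2 0.0847).

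Markers of other cell types were measured to see whether the cells in the libraries differed in kind. Of 14 basal epithelial markers, 6 were lower, with the laminin genes LAMC2 (-0.91 ± 0.06) and LAMA3 (-0.66 ± 0.06) and TRIM29 (-0.31 ± 0.06) among them, and SFN (0.39 ± 0.06), CAV1 (0.23 ± 0.07) and KRT16 (0.75 ± 0.17) were higher (adjusted over the list alone, 7 lower and 3 higher). SFN is also a known p53 target. The camera adjusted p was 0.0309 (adjusted p = 0.618 with an estimated correlation), and the call also ended with no filter (0.141), the stricter filter (0.0578), limma on gene-row TMM (0.0885), quantile normalization (0.122), C1 (0.0596) and P1 (0.294). Among 6 tested immune markers, ITGAM fell (-0.93 ± 0.12) and CORO1A rose (0.29 ± 0.10), while CD68 (0.30 ± 0.14) and CSF1R (-0.89 ± 0.44) were not called (adjusted over the list alone, 1 higher and 1 lower; camera adjusted p = 0.711). Of 5 endothelial markers CDH5 fell (-0.64 ± 0.14), and ENG (-0.54 ± 0.37), ESAM (-0.39 ± 0.27) and ERG (0.17 ± 0.44) were not called (adjusted over the list alone, 0 higher and 1 lower; camera adjusted p = 0.447). None of 5 stromal markers was called in edgeR, FBLN1 having the smallest unadjusted p, 0.0325 (-1.08 ± 0.47; adjusted over the list alone, 0 higher and 0 lower; camera adjusted p = 0.460); COL3A1 was at -0.77 ± 0.38, COL6A3 at -0.43 ± 0.26 and COL1A1 at 0.08 ± 0.14. Under an alternative the call ended for CORO1A (DESeq2 0.170, C2 0.327 at 0.18, P1 0.148) and CAV1 (DESeq2 0.112, C1 0.0527, C2 0.161). An alternative gave a call for CD68 (C2 0.0169 at 0.53) and FBLN1 (P2 0.0419 at -1.83), but other leave-outs moved them the opposite way, CD68 to 0.06 (C1) and FBLN1 to -0.61 (P1). Values that were not called moved as well: ENG to -0.05 (C1) and -0.85 (C2), ERG to -0.26 (C1), 0.67 (C2), 0.43 (P1) and -0.16 (P2), COL6A3 to -0.18 (C1) and -0.27 (P2), and COL1A1 to 0.16 (P1) and 0.00 (P2).

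The third comparison asked whether TE transcripts differed, since SETDB1 is known to silence these elements. TE rows as a group were higher with P-SETDB1-4: 460 of 1017 tested rows were higher and 5 were lower, and 900 had a positive log2 change. Among the 1017 are 18 satellite rows, of which 9 were higher, the 7SK row, also higher, and 13 rows of unknown class. Adjusted over the TE rows alone, 506 were higher and 8 lower. TE rows took 5.36% (95% Wilson interval 5.35 to 5.37) and 5.33% (5.32 to 5.34) of the counts in the control libraries and 6.69% (6.68 to 6.70) and 6.44% (6.43 to 6.45) in the P-SETDB1-4 libraries, a ratio of group means of 1.23. An exact permutation test of 2 libraries against 2 cannot go below a two-sided p of 0.333, the value found here.

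The class with the largest gain in share was SINE, whose rows took 2.04 ± 0.0158% of counts in control and 2.66 ± 0.0466% with P-SETDB1-4 (SD, n = 2 each). Of 57 SINE subfamilies 50 were higher and 0 were lower, with a median log2 change of 0.43, and the abundant AluSx1 rose from 1472 ± 4.70 to 2024 ± 19.6 CPM (0.46 ± 0.03, edgeR adjusted p = 1.55e-07). LINE rows had 94 of 155 higher and 1 lower (median 0.24), and DNA transposon rows 113 of 213 higher and 1 lower (median 0.32). LTR rows, which derive from endogenous retroviruses, had 183 of 542 higher and 3 lower (median 0.25), and satellite rows 9 of 18 higher and 0 lower (median 0.48). Adjusted over the list alone, the higher and lower counts were 51 and 0 for SINE, 106 and 1 for LINE, 132 and 1 for DNA, 195 and 3 for LTR and 10 and 0 for satellite rows. Camera called each of these classes (adjusted p from 1.01e-45 for SINE to 8.62e-08 for satellites), but none with an estimated correlation (adjusted p = 0.286 with an estimated correlation for SINE and for satellite, 0.310 for LTR, 0.424 for DNA and 0.548 for LINE rows). fry called SINE (0.0229), LTR (0.0310) and satellite rows (0.0173), and not DNA (0.0676) or LINE rows (0.10).

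The TE rows with the smallest p were the satellite MSR1, from 23.5 ± 2.47 to 60.0 ± 3.54 CPM (1.34 ± 0.07), FordPrefect of the DNA class (1.497 ± 0.09), the retroviral repeats LTR12C, from 266 ± 0.694 to 536 ± 74.5 CPM (1.01 ± 0.07), and MER66D (2.89 ± 0.19), AluSx1, and the satellite SATR1 (1.27 ± 0.09). The rows called lower were MER97d (-0.53 ± 0.10), L1M3de (-0.55 ± 0.13), LTR1B (-0.41 ± 0.09), MER4A (-0.30 ± 0.08) and MER70B (-0.31 ± 0.09), and LTR46-int (-0.27 ± 0.10) was not called. The rows L1HS, SVA_D, HERVH-int and HERVK-int were named in advance. L1HS, the youngest human L1 subfamily, rose by 0.15 ± 0.04, SVA_D by 0.24 ± 0.05 and HERVH-int by 0.14 ± 0.05, whereas HERVK-int (0.21 ± 0.10) did not pass (edgeR adjusted p = 0.120). In the young L1 list L1HS, L1PA7 (0.12) and L1PA8 (0.17) were the 3 of 8 called higher, with 0 lower (median 0.07; adjusted over the list alone, 3 and 0; camera adjusted p = 0.344). Calls that an alternative ended, with the adjusted p, were those of L1PA7 (replicate block 0.0549, DESeq2 0.0850, C1 0.244, C2 0.215, P1 0.0757, totals 0.0599), MER70B (DESeq2 0.120, C1 0.0743, C2 0.0676, P1 0.133 at -0.19), HERVH-int (DESeq2 0.0925, C1 0.199, C2 0.183, P1 0.114 at 0.09), L1PA8 (DESeq2 0.113, C1 0.114, C2 0.180, P1 0.283 at 0.07, totals 0.0512) and L1HS (C1 0.247, C2 0.0606). Called under an alternative were LTR46-int (no filter 0.0495, quantile 0.0312, totals 0.0476). A left-out library moved MER4A to -0.17 and L1PA8 to 0.27 without P-SETDB1-4 replicate 2, and the uncalled HERVK-int to 0.13 without P-SETDB1-4 replicate 1.

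**Figure D3:**
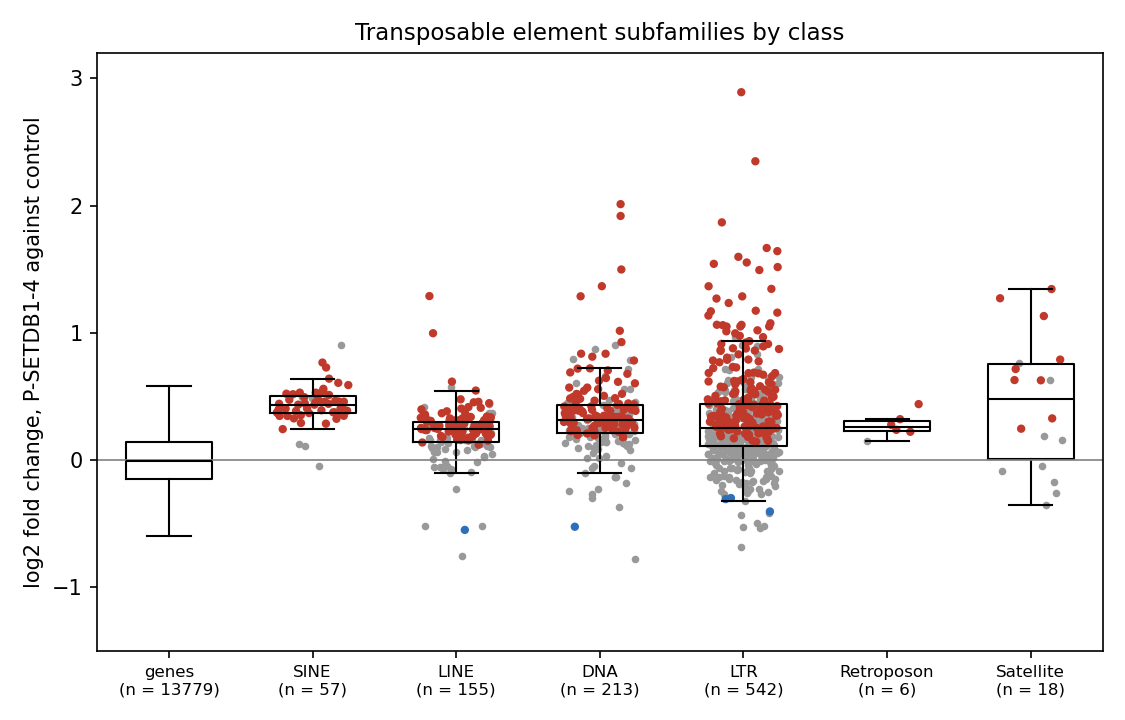
Log2 change of P-SETDB1-4 over control for each tested TE subfamily of 6 classes (points; red, called higher; blue, called lower; grey, not called), with boxes for the median and quartiles and a box for the 13779 tested genes at left; whiskers reach up to 1.5 times the interquartile range. The gene box centres near 0 and the medians of the 6 classes shown lie above it, from 0.24 for LINE to 0.48 for satellite rows.

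Within LTR rows, the ERV1 family had 106 of 285 subfamilies higher and 2 lower (median 0.33; adjusted over the list alone, 117 and 4), and camera called it (adjusted p = 1.80e-11; adjusted p = 0.286 with an estimated correlation). ERVK had 11 of 37 higher and 0 lower (median 0.20; list alone 11 and 0; camera adjusted p = 0.00330, or adjusted p = 0.424 with an estimated correlation). ERVL had 28 of 116 higher and 1 lower (0.22; list alone 22 and 1; camera adjusted p = 0.000134, or adjusted p = 0.286 with an estimated correlation), and ERVL-MaLR 32 of 78 higher and 0 lower (0.21; list alone 34 and 1; camera adjusted p = 5.08e-06, or adjusted p = 0.530 with an estimated correlation). Gypsy (5 of 21 higher, 0 lower; list alone 5 and 0; camera adjusted p = 0.0551) and the 5 rows annotated only as LTR (1 higher, 0 lower; list alone 1 and 0; camera adjusted p = 0.346) were not called. Internal regions of endogenous retroviruses had 34 of 130 higher and 0 lower (median 0.23; list alone 30 and 0; camera adjusted p = 0.000239, or adjusted p = 0.424 with an estimated correlation), and SVA rows, the only Retroposon rows, 5 of 6 higher and 0 lower (median 0.26; list alone 6 and 0; camera adjusted p = 0.00424, or adjusted p = 0.384 with an estimated correlation). The count of higher TE rows fell to 287 with DESeq2 and to 43 with limma on unscaled values. A subfamily shares reads with its close relatives, so the number of rows called is not a number of separate events.

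Gene families known to be repressed by SETDB1 in other cells were measured as well. Of 427 ZNF-named zinc finger genes 56 were higher and 28 lower (adjusted over the list alone, 48 and 19; camera adjusted p = 0.190). ZNF217 rose from 911 ± 29.9 to 1304 ± 22.8 CPM (0.52 ± 0.04), ZNF24 (0.52 ± 0.05) and ZNF580 (0.79 ± 0.08) rose, and ZNF462 fell (-0.84 ± 0.09). Of 47 clustered protocadherin genes PCDHA11 (0.38 ± 0.10) and PCDHGC3 (0.35 ± 0.11) were higher, while PCDHA13 (0.38 ± 0.14) and PCDHB2 (0.34 ± 0.15) were not called (adjusted over the list alone, 0 higher and 0 lower; camera adjusted p = 0.447). Among 11 germline and cancer-testis genes edgeR called 0 higher and 0 lower, also adjusted over the list alone, and SYCP2 (0.24 ± 0.09), with an unadjusted p of 0.0186, came closest (camera adjusted p = 0.993). The others with the smallest p were MEIOB (0.66 ± 0.35), TEX19 (-0.39 ± 0.22) and MAGEC1 (-0.24 ± 0.16). An alternative ended the call of PCDHGC3 (quantile 0.0513, DESeq2 0.146, C2 0.196, P1 0.196 at 0.22) and PCDHA11 (DESeq2 0.0852, C1 0.213 at 0.24). An alternative gave a call for PCDHA13 (no filter 0.0450, stricter filter 0.0465, gene-row TMM 0.0481, limma on gene-row TMM 0.0488, P2 0.0450), SYCP2 (stricter filter 0.0457, gene-row TMM 0.0455) and PCDHB2 (P1 0.0480). Among uncalled values, PCDHB2 moved to 0.22 (C2) and 0.20 (P2), TEX19 to -0.25 (P1), and MAGEC1 to -0.36 (P1) and -0.12 (P2).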

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

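The counts, list results and SETDB1 level were recomputed under each alternative; median-of-ratios factors, library totals, limma on log2(count + 1) and the leave-outs of the TE share were tests chosen after the data had been seen. Limma on unscaled log2 values gave far fewer calls. It called 167 genes higher and 66 lower, 44 TE rows higher and 0 lower, with SETDB1 at -0.237 (adjusted p = 0.872), at a pseudocount of 0.5; 170, 64, 46 and 0, with SETDB1 at -0.236 (0.869), at a pseudocount of 8; 165, 66, 43 and 0, with SETDB1 at -0.237 (0.872), on log2(count + 1); and 337, 177, 94 and 3, with SETDB1 at -0.237 (0.878), without the trend. For the runs with the trend the missing depth scaling is the cause, since limma on values scaled by TMM factors from gene rows called 1966 and 2107 genes and 489 and 5 TE rows with the trend; without the trend the cause was not tested. Over the scaled alternatives SETDB1 passed with adjusted p from 0.000376 to 0.0334. DESeq2 called 953 and 1441 genes and 287 TE rows higher; the cause was not tested. The 5 lower TE rows became 8 without a filter, with library totals and when TE rows were adjusted alone, and 9 with quantile normalization; the cause was not tested. Camera's 17 higher lists and 3 lower lists became 0 and 0 with an estimated correlation, and fry called 10 and 1. The p53 and H3K9 lists had estimates of -0.0251 and -0.0286, below the preset 0.01. Their calls were still lost, the unadjusted camera p of the p53 list going from 8.95e-36 to 0.00466. Other lists had estimates above the preset, such as immediate early genes (0.345). A call lost in that run, which has few residual degrees of freedom, therefore does not by itself show correlated members. The lower lists were 1 on unscaled values at a pseudocount of 0.5, on log2(count + 1), without the trend, with a mean of at least 50 counts and with quantile normalization; the cause was not tested.

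Leaving out each library in turn, with the lone library assumed to vary like the other group, gave 1051 to 1993 genes higher, 1287 to 2498 lower, 332 to 483 TE rows higher and 4 to 8 lower, 17 to 19 lists higher and 0 to 3 lower, SETDB1 at -0.295 to -0.19 and a TE share ratio of 1.204 to 1.252. The lower lists fell to 0 without P-SETDB1-4 replicate 1, and the lower TE rows reached 8 without P-SETDB1-4 replicate 2. The lowest gene counts came without a control library, where the spread was taken from the P-SETDB1-4 pair alone. That pair had the larger chi-square per degree of freedom, 3.05 against 1.49 for the controls. Whether this is the whole cause was not tested. The replicate numbers are shared by the groups, but no label says that they pair samples, and deviations of same-numbered libraries correlated at -0.0281. With the number as a replicate block, 1693 genes were higher and 2203 lower, 462 TE rows higher and 6 lower, lists were 17 and 3, and SETDB1 was at -0.241 (adjusted p = 0.00438); of the named rows CDC45 (0.0646), MCM5 (0.0691) and L1PA7 (0.0549) no longer passed.

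Over 13 alternatives on scaled values or counts, 2474 of 2683 values for the named genes and TE rows kept direction and side of the threshold, 177 lost the call, 24 gained it and 8 changed sign. The sign changes were in CRBN (0.005 and 0.002 with TMM factors from gene rows in edgeR and limma, 0.060 without control replicate 2, 0.048 without P-SETDB1-4 replicate 2, against -0.083 without control replicate 1), COL1A1 (-0.005 with quantile normalization) and ERG (-0.261 without control replicate 1, -0.160 without P-SETDB1-4 replicate 2, against 0.668 without control replicate 2), none of them called; and in MT-CYB (0.000 with quantile normalization, which sets a row equal where its rank is equal; by count it had rank 9 in each library). The calls lost were most in number without control replicate 1 (43) or 2 (45) and with DESeq2 (31). In the simulated data, of the changed genes with a mean under 50 counts, 0 of 5 raised 1.5-fold, 1 of 7 lowered to 0.667, 3 of 4 raised 2-fold and 1 of 6 lowered to 0.5 were called, so changes in such genes can be missed.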

Other observations

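The tests of technical explanations in this part all concern patterns already seen in these data, and none was part of the design. Predictions on GC content and on the span of p53 target genes were written before those tests, and the other predictions after. The gene lists were fixed before the data were examined.

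Other gene groups moved in both directions. In the epithelial junction and keratin list 7 of 28 genes were higher and 8 lower (adjusted over the list alone, 9 and 9; camera adjusted p = 0.633): the tight junction scaffold gene TJP1 fell by 0.67 ± 0.05, KRT7 by 0.39 ± 0.05 and the epithelial transcription factor gene GRHL2 by 0.29 ± 0.05, and CLDN4 rose by 0.39 ± 0.04. Of 27 mesenchymal genes, SERPINE1 (1.04 ± 0.22), SNAI1 (0.69 ± 0.16), ACTA2 (0.53 ± 0.12), CCN2 (0.38 ± 0.12) and THBS1 (0.21 ± 0.05) were higher, and SNAI2 (-0.80 ± 0.16), TGFB2 (-0.36 ± 0.05), ITGB1 (-0.34 ± 0.04), CCN1 (-0.22 ± 0.06) and FN1 (-0.15 ± 0.05) lower (adjusted over the list alone, 5 and 5; camera adjusted p = 0.611). Of 33 lysosome and autophagy genes 6 were lower, with the transcription factor gene TFE3 (-0.76 ± 0.06), the autophagy receptor genes OPTN (-0.63 ± 0.07) and SQSTM1 (-0.43 ± 0.05) and HEXB (-0.30 ± 0.05), and GABARAPL1 (0.74 ± 0.22), NEU1 (0.31 ± 0.06), NPC2 (0.22 ± 0.05) and CTSL (0.18 ± 0.04) were higher (adjusted over the list alone, 6 lower and 4 higher; camera adjusted p = 0.292). In the hypoxia and glycolysis list 7 of 31 genes were lower, among them ADM (-0.56 ± 0.09), P4HA1 (-0.48 ± 0.07), HK1 (-0.27 ± 0.04) and PFKP (-0.24 ± 0.04), and PGAM1 (0.20 ± 0.04) was higher (adjusted over the list alone, 7 and 1; camera adjusted p = 0.312). No longer called under an alternative were CCN2 (quantile 0.0597, DESeq2 0.180, C1 0.0656, C2 0.115, P1 0.118), ACTA2 (DESeq2 0.0585), CCN1 (DESeq2 0.0674, C1 0.128, C2 0.0617), GABARAPL1 (DESeq2 0.154, C2 0.143, P2 0.0531), THBS1 (C1 0.0859), FN1 (C1 0.0801, C2 0.242), CTSL (C1 0.0572, C2 0.0875), PGAM1 (C2 0.102) and NPC2 (C2 0.106).

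Of 25 PI3K-AKT and mTOR genes 9 were lower, including DEPTOR (-0.43), RHEB (-0.28) and INPP4B (-0.21), and SGK1 (0.50) and DDIT4 (0.33) were higher (adjusted over the list alone, 9 and 2; camera adjusted p = 0.239). In the unfolded protein and integrated stress response list 7 of 38 genes were higher, including SESN2 (0.58), DDIT4, SLC3A2 (0.24) and SYVN1 (0.22), and EDEM1 (-0.25), ATF4 (-0.20) and SLC7A5 (-0.15) lower (adjusted over the list alone, 7 and 3; camera adjusted p = 0.162). Heat shock genes had 9 of 22 higher, with HSPA1B (0.52), DNAJA1 (0.24) and HSP90AA1 (0.18), and HSPA4 (-0.39), HSF2 (-0.31), HSF1 (-0.18) and STIP1 (-0.18) lower (adjusted over the list alone, 10 and 7; camera adjusted p = 0.451, but 0.0180 for P1). Cholesterol synthesis genes had 6 of 27 higher, with LDLR (0.38), HMGCR (0.23), DHCR7 (0.20) and IDI1 (0.20), and SREBF2 (-0.16) lower (adjusted over the list alone, 6 and 1; camera adjusted p = 0.346). Nuclear genes of oxidative phosphorylation had 21 of 74 higher and 8 lower, with ATP5MC1 (0.40) and ATP5PD (0.33) up and NDUFB5 (-0.61) and COX5A (-0.31) down (adjusted over the list alone, 23 and 8; camera adjusted p = 0.239, but 0.0203 with quantile normalization and 0.0299 for P2). Of 13 mRNAs encoded by mitochondrial DNA, MT-ND6 (0.23), MT-ATP8 (0.15), MT-ND5 (0.15), MT-CYB (0.13) and MT-ND4L (0.10) were higher and MT-CO2 (-0.12) lower (adjusted over the list alone, 5 and 1; camera adjusted p = 0.206, but 0.0320 for P1); with quantile normalization MT-CYB was at 0.000. TUG1, the single tested member of the noncoding RNA list, fell by 0.15 ± 0.04 (edgeR adjusted p = 0.00745). Under an alternative the call ended for HSP90AA1 (quantile 0.187 at 0.06), MT-ND5 (quantile 0.106 at 0.05), MT-ATP8 (quantile 0.421 at 0.03, C1 0.0558), HSF1 (quantile 0.0898, DESeq2 0.0912, C1 0.0990, C2 0.176, P1 0.176 at -0.10), SREBF2 (quantile 0.0574, DESeq2 0.0766, C1 0.193, C2 0.135), MT-CYB (quantile 1 at 0.00, C1 0.0721), MT-ND4L (quantile 0.485 at 0.02, DESeq2 0.0831, C1 0.337, C2 0.0562, P2 0.135 at 0.06, totals 0.0602), DEPTOR (DESeq2 0.0509, C2 0.0946), HSPA1B (DESeq2 0.117), SGK1 (DESeq2 0.125, C2 0.122, P2 0.0914), ATF4 (DESeq2 0.101), HSF2 (DESeq2 0.216, C1 0.314, P1 0.0529, P2 0.0906), HMGCR (C1 0.0517), IDI1 (C1 0.0892), INPP4B (C2 0.135), MT-CO2 (C2 0.0505), SLC7A5 (C2 0.114), EDEM1 (C2 0.114) and STIP1 (C2 0.0685). A left-out library moved ATF4 to -0.11 without P-SETDB1-4 replicate 1, HSPA1B to 0.26 without P-SETDB1-4 replicate 2 and HSF1 to -0.28 without P-SETDB1-4 replicate 2.

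TE rows rose as a group, and the tables argue against scaling, since with factors from gene rows alone the median TE log2 change was 0.288. Genomic DNA stays open. Near-silent genes gained 3.13 CPM in sum (SD of the difference 3.56), where evenly spread genomic reads would have added at least 26.0. That amount is a lower bound, since it spreads the gain on TE rows over the whole genome. These genes were chosen on all 4 libraries, which leaves out genes that rose with P-SETDB1-4. Chosen on the controls, which favours genes that happened to be low there, such genes gained 49.7 CPM against an expected 25.7. Chosen on 1 control library and measured against the other, they gained 22.4 and 32.2 CPM, against an expected 22.6 and 26.6. The outcome thus depended on how the genes were chosen. A general rise of repeat-bearing RNA, such as retained introns or transcripts running past gene ends, may account for the shared shift. Of the rows of the DNA class, which no longer transpose, 92.5% had a positive change, as had 468 of 542 LTR rows and 140 of 155 LINE rows. A row need not transpose to be transcribed, so this share does not set such a rise apart from a loss of silencing. How many rows a general rise covers was not settled. In an edgeR test against the DNA class median of 0.315, at an adjusted p under 0.05 over the TE rows, 78 of 1017 TE rows were called above it and 88 below it. Of those above, 31 were ERV1, 16 Alu and 13 of the DNA class itself. The share of each subfamily's copies in introns or past gene ends was not measured. A loss of SETDB1 silencing stays open as an untested hypothesis, since the counts lack positions.

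Genes with long spans tended to be lower and those with short spans higher (Spearman rho across genes -0.360, where genes are not independent replicates). The median of the shortest-span group minus that of the longest was -0.099 and -0.137 in the control libraries. In the P-SETDB1-4 libraries it was 0.086 and 0.152, each relative to the row mean. Degradation that removes long mRNAs is argued against by a difference of at least 0.172 between these groups at similar exon length. Exon length here joined the exons of all isoforms, so it is not the length of the expressed mRNA. GC content is argued against by a difference of at least 0.146 at similar GC. Noise of low genes is argued against by a correlation of -0.402 among genes with a mean of at least 50 counts. The group with the longest exons held only 9 short-span genes, and without it the smallest difference was the same 0.172. In each span group, genes with 2 to 6 exons had a higher median than genes with over 10 exons, by 0.022 to 0.126. From the shortest to the longest spans, the median went from 0.108 to -0.023 with 2 to 6 exons. With over 10 exons it went from 0.068 to -0.149, so span and exon number both went with the change. The span trend does not explain the p53 list, whose median of 0.443 lay above all 10000 random lists of genes of similar span (highest 0.211). Slower elongation or altered processing of long transcripts under P-SETDB1-4 may underlie the trend, and remains untested.

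Most tested histone genes were higher (40 of 57, with 6 lower) although the libraries were made from polyadenylated RNA. Carry-over of RNA without a polyA tail would move them with the 7SK RNA. Between the P-SETDB1-4 libraries, where the 7SK row differed by 0.782, the upper quartile of the histone differences was 0.247 against 0.490 under proportion. That row sums over every 7SK copy in the genome and need not follow the 7SK RNA itself. The comparison therefore covers only a carry-over that moves with the row. Their intronless form is not enough, since the 40 single-exon histone genes had a median of 1.016. The highest median of 10000 lists of other single-exon genes of similar expression was 0.411. Those lists were not matched on span, so the short length of histone genes was not tested. The 230 other single-exon genes also leaned upward, with 68 higher and 5 lower. A change in the polyadenylation of histone transcripts was not tested and stays open, as does a carry-over that the 7SK row does not track.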
